A study of Mus musculus with 3 samples.

How the data were processed

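Gene expression was measured in single nuclei of gastrocnemius muscle from wild-type female C57BL/6 mice. The labels describe 3 groups: mice aged 3 months given phosphate-buffered saline, mice aged 20 months given the same vehicle, and mice aged 20 months given ginkgolide B at 12 mg per kg body weight daily by oral gavage, each for 8 weeks. Whether these ages are those at the start or at collection is not given in the sources used here. Muscle was minced and homogenised, nuclei were stained with DAPI and sorted, nuclei of 2 mice were pooled per library, and a droplet kit that reads the 3' end of transcripts was used. There was 1 library per group, so the group and the library cannot be separated.

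The deposited files hold UMI counts, that is, numbers of distinct transcript molecules per gene and nucleus barcode, not normalized. Per the submitters' processing notes, the authors made them with Cell Ranger 7.0.1 on the mouse build mm10. Whether intronic reads were counted is not given in the sources used here. The files hold 32285 genes and 2128, 2015 and 1929 barcodes for the young vehicle, aged vehicle and aged ginkgolide B (GB) libraries, with total counts of 4705952, 4263506 and 4895230 UMIs. The lowest barcode has 504, 500 and 500 UMIs in the same order. Gene coordinates come from GENCODE vM21 on the same build, matched by gene ID for 32158 of the 32285 genes.

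Nuclei with at least 200 genes and at most 5% mitochondrial UMIs were kept, which removed 18 barcodes. Scrublet, run within each library in scanpy 1.11.5, called 40 doublets, or 0.471%, 0.547% and 0.989% of barcodes, and these were removed. The remaining 6014 nuclei were log-normalised to 10000 UMIs and clustered together without batch correction, using 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 (igraph 0.11.9, Python 3.11.15). The 24 clusters were named from marker genes fixed before the data were examined: a name needed at least 3 markers that were detected in 10% of the cluster's nuclei and were 2-fold higher than in other clusters. After the clusters were seen, a cluster led by Cldn1 and Moxd1 was left unnamed, and clusters with over 40000 CPM (UMIs of a gene or gene set scaled to an equal class total) of shared muscle transcripts and no other name were called unnamed myonuclei. These are reclustered names and can differ from the names the authors used.

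UMIs were summed per library and class, and compared as log2 ratios of CPM with an exact conditional binomial interval (scipy 1.17.1). Classes with at least 30 nuclei in every library were compared. All myonuclei together were added as a class after the data were seen, because the unnamed myonuclei hold different clusters in the libraries. Shares have exact Clopper-Pearson intervals. All intervals are at 95%. They cover counting error only, except where nuclei were resampled or a share was taken over genes. Without replicate libraries, no p-value, standard error or number of changed genes was computed, and no replicate check of any difference exists. Where a library had 0 counts, the ratio was bounded with a floor of 3 counts over the class. No paired or batch design could be formed.

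Named genes followed a size rule set before the data were examined. In type IIb myonuclei these were the 10 highest and 10 lowest log2 ratios among genes with at least 100 summed UMIs. In other classes they were the 3 highest and 3 lowest among genes with at least 50. The text gives these for the comparisons with aged vehicle, and for aged GB against young vehicle only over all myonuclei. The largest members of each gene list and Runx1, the 4 adult myosin heavy chains, Ptafr and Cdkn1a were added. Mitochondrial genes, ribosomal protein genes and gene models without a proper name were left out. Some genes that the rule selects are not reported here. Other genes were chosen after their values were seen: Cish, Socs2 and Eda2r in type IIb myonuclei, the summed clock genes, and Fkbp5 and Pdk4 in classes where the rule did not name them.

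The 20 gene lists, also fixed beforehand, cover denervation, atrophy and ubiquitin ligases, autophagy, mitochondria, fatty acid metabolism, glycolysis and fast and slow contractile genes. They also cover calcium handling, apoptosis, senescence, extracellular matrix, the circadian clock, immediate early and handling stress genes, insulin signalling and oxidative stress. The remaining lists are interferon and inflammation, the platelet-activating factor pathway, satellite cells and the dystrophin complex. For each list the median log2 ratio of members with at least 20 summed UMIs was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. Shares of nuclei with a UMI were compared after thinning each nucleus to 1000 UMIs, leaving out shallower nuclei, beside the share in endothelial nuclei as a measure of free RNA.

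The ratio and list steps were tested on simulated counts drawn from the real type IIb profiles and depths, with 200 genes altered. In the aged vehicle against young vehicle simulation, run on 3672 genes, the interval held the true value for 95.6% of unaltered genes, and all 4-fold genes (100%) came out at least 2-fold apart, as did 58.1% of 2-fold genes. In the aged GB against aged vehicle simulation, on 2962 genes, these figures were 96.2%, 100% and 45%, with the true value held for 90% of 2-fold genes, and in the aged GB against young vehicle simulation, on 3545 genes, 95.5%, 100% and 52.4%. Of 200 simulated lists of 14 genes raised 1.5-fold, 99.5%, 100% and 100% passed percentile 97.5 in the same order of comparisons, against 2%, 1% and 3.5% of unaltered lists. The rise was added to the ratios after the counts were drawn. The draws hold counting error only, so these figures do not cover genes that vary together or differences between libraries.

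Alternatives covered the filter on nuclei, doublets, clustering resolution, principal components, clustering without list genes, classes from marker scores, 3 other scalings, thinning, all nuclei of a library, and the minimum UMIs of a gene. Clustering without the 100 leading genes of a Runx1-high cluster was added after the data were seen.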

Results

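The data describe the transcripts of single nuclei from the gastrocnemius, a mainly fast calf muscle, in young and aged female mice. The aged mice received either vehicle or ginkgolide B (GB), a terpene lactone from Ginkgo biloba that blocks the receptor of platelet-activating factor. The young vehicle, aged vehicle and aged GB groups were represented by 1 library each, made from nuclei of 2 mice. After filtering, 2112, 2000 and 1902 nuclei remained, with medians of 1975, 1766 and 2068.5 UMIs and 1016.5, 922.5 and 1061 genes per nucleus. Values below are given in this order of libraries.

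Nuclei of muscle fibres (myonuclei), connective tissue, vessels, immune cells, fat and nerve were all recovered. The sort kept any DAPI-stained nucleus, so shares describe sorted nuclei and not the tissue. Myonuclei made up 49.8% (interval 47.6 to 51.9), 59.8% (57.6 to 61.9) and 46.2% (44.0 to 48.5) of nuclei. Type IIb-like myonuclei, the fastest and most glycolytic kind, made up 32.9% (30.9 to 34.9), 28.8% (26.8 to 30.8) and 20.3% (18.5 to 22.2). Within myonuclei the type IIb share was 66.0%, 48.2% and 43.9%. Under other clustering settings the type IIb share ranged widely, and with 15 principal components it was 37.5%, 39.4% and 28.4%, so that the aged vehicle library no longer stood below the young one. Type IIx/IIa-like myonuclei made up 7.67%, 11.4% and 9.88%, and type I-like myonuclei of slow fibres 0.758%, 1.75% and 1.47%. Myonuclei at the tendon junction made up 2.89%, 4.25% and 3.52%, and those at the neuromuscular junction 0.994%, 1.00% and 0.841%. With at least 500 genes per nucleus, where a Runx1-high cluster takes that name, the share of neuromuscular junction myonuclei was 1.03%, 7.10% and 3.98%. Unnamed myonuclei made up 4.59%, 12.6% and 10.2%.

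Among the other nuclei, fibro-adipogenic progenitors, the connective tissue cells that make matrix and fat, held 22.5%, 19.7% and 21.6%. Tenocyte-like nuclei, from tendon, held 4.55% (96 nuclei), 0.75% (15 nuclei) and 1.21% (23 nuclei). The amount of tendon taken with the muscle can set this share. Satellite cells, the stem cells of muscle, held 2.37% (1.76 to 3.11), 1.45% (0.973 to 2.08) and 1.37% (0.895 to 2.00). Endothelial nuclei held 8.38%, 7.60% and 12.4%, mural nuclei 4.73%, 3.30% and 4.68%, and macrophages and monocytes 3.22%, 3.15% and 5.36%. Adipocytes held 1.66%, 2.10% and 3.26%, and Schwann cells 1.28%, 1.25% and 1.89%. Lymphocytes numbered 3, 5 and 7 nuclei. The unnamed non-muscle cluster led by Cldn1 and Moxd1 numbered 30, 14 and 31.

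**Figure D1:**
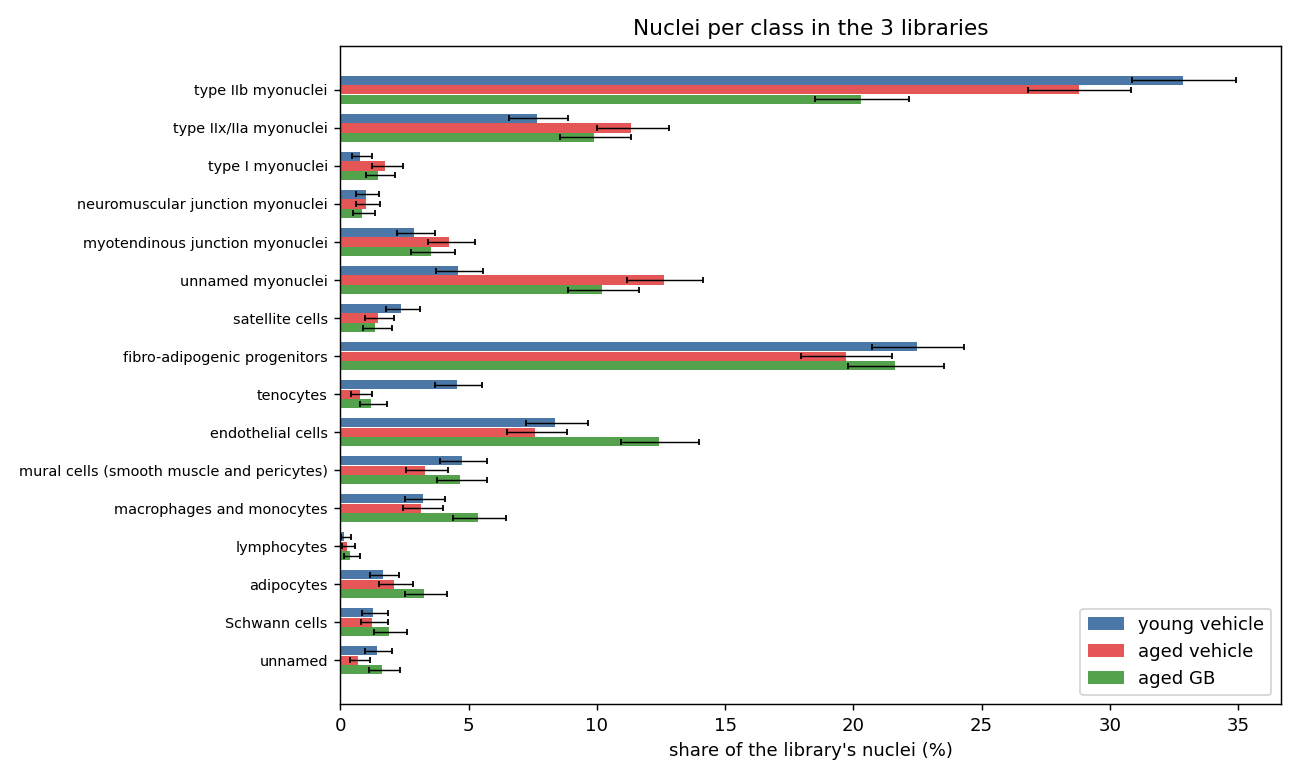
Share of each library's nuclei (%, x axis) in each class (y axis), with bars for the 3 libraries and exact 95% binomial intervals that cover counting error only. Type IIb myonuclei stand at 32.9%, 28.8% and 20.3%, and tenocytes at 4.55%, 0.75% and 1.21%, in young vehicle, aged vehicle and aged GB.

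The fibre-type makeup was followed through the myosin heavy chains, the motor proteins that set contraction speed. Over all myonuclei, Myh4, the type IIb myosin, was at 3964, 2636 and 3029 CPM. Myh1, the type IIx myosin, was at 516, 689 and 976 CPM, Myh2 of type IIa fibres at 595, 656 and 1002 CPM, and the slow myosin Myh7 at 102, 140 and 194 CPM. At 1000 UMIs per nucleus, 80.7%, 63.9% and 65.1% of myonuclei had a Myh4 UMI, beside 35.8%, 17.5% and 33.5% of endothelial nuclei, and 12.5%, 18.3% and 21.8% had a Myh1 UMI, beside 2.11%, 1.25% and 4.35%. For Myh2 the shares were 12.9%, 15.3% and 17.2%, beside 9.47%, 7.50% and 6.83%, with intervals that overlap in young and aged vehicle. For Myh7 they were 1.90%, 3.22% and 4.05%, beside 1.05%, 3.75% and 1.24%, with intervals that overlap in every library. Median depths before thinning were 2787, 2579.5 and 3423.5 UMIs in the myonuclei used and 1531, 1473.5 and 1639 in the endothelial nuclei. Thinning left out 50, 169 and 89 myonuclei and 82, 72 and 75 endothelial nuclei.

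The first comparison, aged vehicle against young vehicle, asks how the muscle of aged mice differs from that of young mice. In type IIb myonuclei of the aged library, Chrm3 and Wnt5b were highest and the fatty acid list, led by Pdk4, stood high, while Mettl21c, Peg3 and Fkbp5 were lowest or among the lowest. Runx1, a transcription factor that muscle makes when it loses its nerve, was far higher when all myonuclei were pooled, with other genes of the denervation response, and 552 of its 666 UMIs in aged vehicle lay in the unnamed myonuclei. Clock genes stood apart in muscle and in connective tissue nuclei.

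In type IIb myonuclei, 59 of 3683 genes with at least 100 UMIs were at least 2-fold higher and 51 at least 2-fold lower in the aged vehicle library. Scaling without mitochondrial and the 10 most abundant genes gave 72 and 40. Counting error alone gave means of 0.11 and 0.22 in simulated unchanged libraries. These counts go by size and not by a test.

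The highest ratio belonged to Chrm3 (ENSMUSG00000046159, chromosome 13, 9875486 to 10360847), which encodes a muscarinic acetylcholine receptor. It stood at 12.8 CPM in young vehicle and 77.9 CPM in aged vehicle, a log2 ratio of 2.61 (1.96 to 3.30). Over all nuclei of the libraries its ratio was -0.24, on the other side. The secreted signal Wnt5b reached 2.56, the TGF-beta-induced repressor Klf10 2.49, the membrane-traffic gene Dennd5b 2.36, and Nkain2, whose product binds the sodium pump, 2.32. Pde10a, which breaks down cyclic nucleotides, reached 2.13 (1.51 to 2.79). Pdk4 (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), the kinase that turns fibres from glucose to fat oxidation, was at 102 and 396 CPM, a ratio of 1.96 (1.72 to 2.20). The potassium channel subunit Kcnab1 stood at 1.84, and the adhesion gene Pcdh9 at 1.75, though at -0.40 over all nuclei. Eda2r, a receptor tied to muscle wasting that was chosen after its value was seen, was at 43.0 and 121 CPM.

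The lowest ratio belonged to Mettl21c (ENSMUSG00000047343, chromosome 1, 44009408 to 44020034), a muscle methyltransferase, with 111 UMIs in young vehicle and 8 in aged vehicle, a log2 ratio of -3.22 (-4.46 to -2.19). The imprinted gene Peg3 stood at -2.88, Prima1, which anchors acetylcholinesterase, at -2.26, and the stress-response genes Gadd45g and Cebpd at -2.13 and -1.93. Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), a glucocorticoid receptor co-chaperone induced by glucocorticoids, was at 348 and 74.1 CPM, a ratio of -2.23 (-2.55 to -1.92). Glul, which makes glutamine, stood at -1.82, the metabolic regulator Ankrd9 at -1.72, the insulin-signalling subunit Pik3r1 at -1.71 and Mlf1 at -1.66. The growth factor Igf1 had 37 UMIs in young vehicle and 1 in aged vehicle. Socs2 and Cish, brakes on growth hormone signalling, were chosen after their values were seen: Socs2 was at 96.7 and 34.4 CPM, and Cish had 89 UMIs in young vehicle and 0 in aged vehicle, a log2 ratio of at most -4.31.

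**Figure D2:**
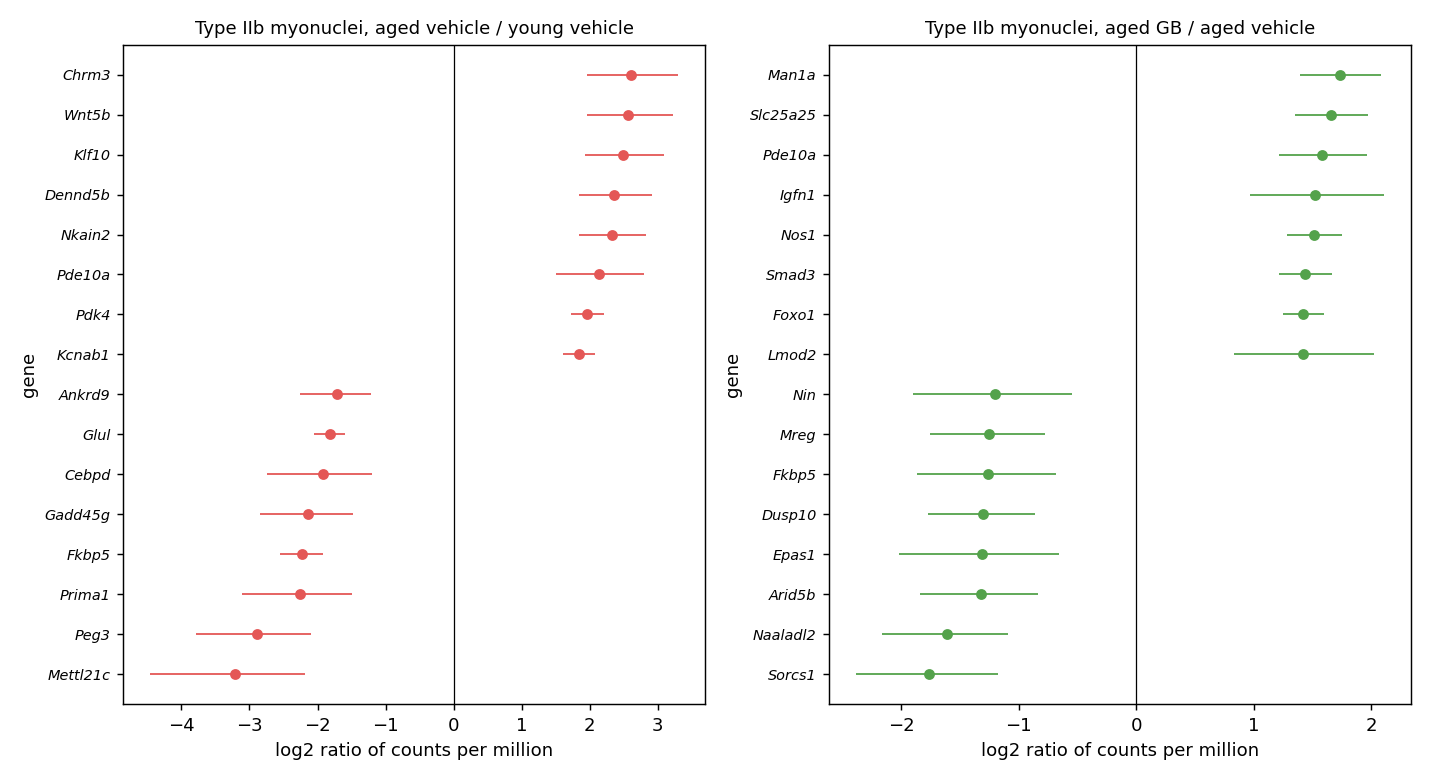
Log2 ratios of CPM (x axis) of the 8 highest and 8 lowest genes (y axis) in type IIb myonuclei, for aged vehicle against young vehicle (left) and aged GB against aged vehicle (right), with 95% intervals that cover counting error only. The left panel runs from Mettl21c at -3.22 to Chrm3 at 2.61 and the right panel from Sorcs1 at -1.76 to Man1a at 1.74.

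Of the gene lists in type IIb myonuclei, fatty acid metabolism stood highest, with a median log2 ratio of 0.90 over 14 members (percentile 100), carried by Pdk4, Fabp3 and Acadl. Fabp3 and Acadl, which carry and oxidise fatty acids, stood at 1.37 and 1.34. The denervation list had a median of 0.71 over the 4 members measured (percentile 99.8), and immediate early genes 0.47 over 5 (percentile 98.7). The circadian clock (-0.34, percentile 0.21), dystrophin complex (-0.32, percentile 0.80), glycolysis (-0.26, percentile 1.10) and calcium handling (-0.24, percentile 4.43) lists stood low. Within glycolysis, Pygm of glycogen breakdown stood at -0.65, while Pfkfb3, which speeds glycolysis, stood at 1.29. Medians for atrophy (-0.21), autophagy (-0.16), mitochondria (-0.10), fast contractile genes (-0.18), apoptosis (-0.13), insulin signalling (-0.08), oxidative stress (-0.08), interferon and inflammation (0.14) and the platelet-activating factor pathway (0.06) lay between percentiles 9.16 and 79.0. Lists with under 3 members measured there were read elsewhere. Over all myonuclei, where the type IIb share differs, the slow contractile list was at 0.54 (percentile 99.98), fast contractile genes at -0.52 (percentile 0.07) and glycolysis at -0.53 (percentile 0). Senescence was at 0.55 over 5 members there (percentile 94.6) and satellite cell genes at 0.51 over 4 (percentile 89.6). Cdkn1a and Myog, members of these lists, are also in the denervation list. In fibro-adipogenic progenitors the extracellular matrix list was at -0.06 (percentile 20.1).

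**Figure D3:**
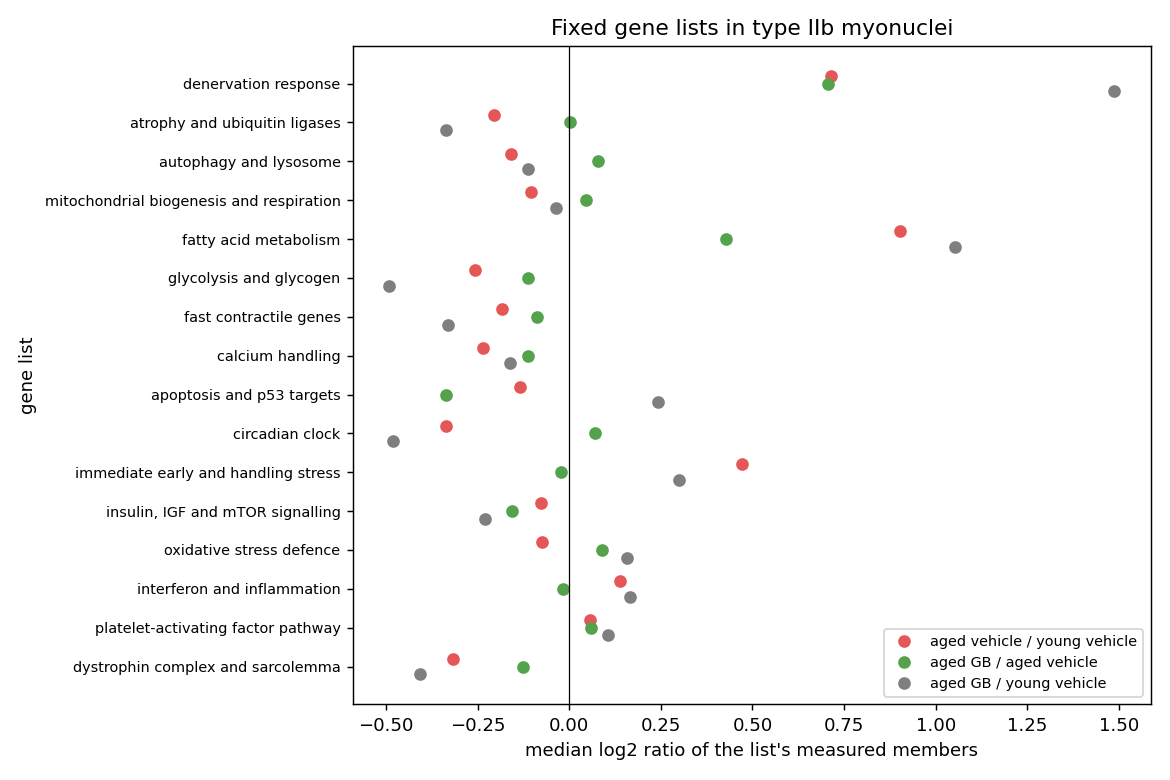
Median log2 ratio (x axis) of the measured members of each gene list (y axis) in type IIb myonuclei, with points for the 3 comparisons. Fatty acid metabolism stands at 0.90, 0.43 and 1.05 in aged vehicle against young vehicle, aged GB against aged vehicle and aged GB against young vehicle.

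Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149, minus strand) was measured as a marker of denervated fibres. Over all myonuclei it had 28, 666 and 420 UMIs, or 9.45 (6.28 to 13.7), 221 (205 to 238) and 141 (128 to 155) CPM in young vehicle, aged vehicle and aged GB. At 1000 UMIs per nucleus, 0.699% (0.282 to 1.44), 9.75% (8.00 to 11.7) and 7.09% (5.40 to 9.11) of myonuclei had a Runx1 UMI. In endothelial nuclei the shares were 0%, 1.25% and 0%, where the upper interval ends of the zeros are 3.81% and 2.27%. Without thinning the shares of myonuclei were 1.81%, 15.4% and 17.0%, and the order of the aged libraries then went against the CPM. Within type IIb myonuclei Runx1 was at 3.07, 26.7 and 43.6 CPM, higher in the aged GB library than in aged vehicle. Macrophages, which use Runx1 in their own development, had 952, 1827 and 1313 CPM.

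**Figure D4:**
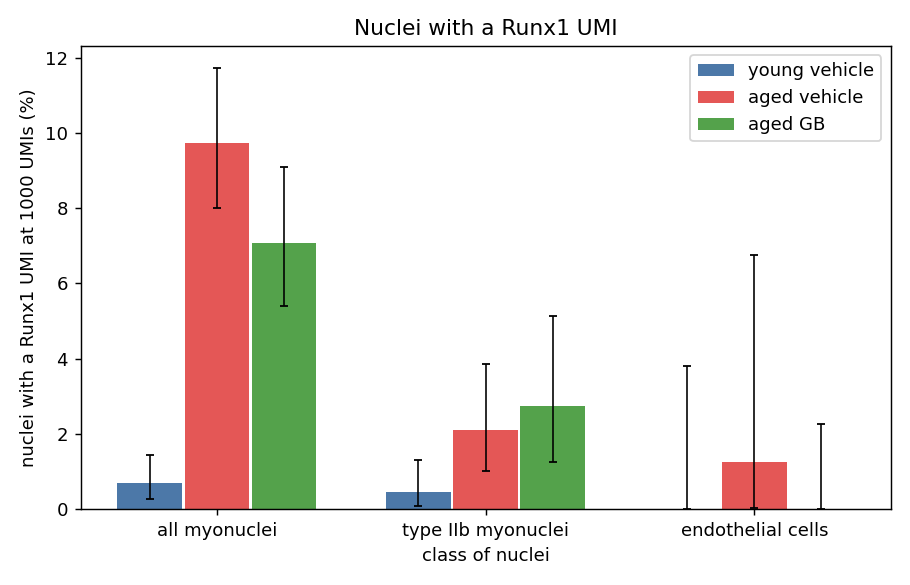
Share of nuclei with a Runx1 UMI at 1000 UMIs per nucleus (%, y axis) in 3 classes (x axis), with bars for the libraries and exact 95% binomial intervals that cover counting error only. All myonuclei stand at 0.699%, 9.75% and 7.09%, and the endothelial background at 0%, 1.25% and 0%.

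Over all myonuclei, Runx1 was at a log2 ratio of 4.55 (4.00 to 5.15) in aged vehicle against young vehicle, beside Rrad, a brake on calcium channels, at 5.68 and Sh3d19 at 5.62. The noncoding imprinted RNA Rian stood at -5.97, Cish at -4.91 and the diacylglycerol kinase Dgkb at -4.73. Of the 10 members of the denervation list measured, 9 were at least 1.5-fold higher in aged vehicle (percentile 100), and without Runx1 the median was 1.20 (1.04 to 1.82), with all 9 members higher. Among them were the acetylcholine receptor subunits Chrna1 and Chrnb1 and Myog, Ncam1, Gadd45a, Musk, Hdac4 and Cdkn1a. The p53 target Cdkn1a, which stops the cell cycle, was at 5.06, 11.6 and 14.5 CPM in the 3 libraries. The unnamed myonuclei are made of clusters that differ between libraries: cluster 5 held 92, 110 and 129 nuclei, and cluster 22 held 5, 142 and 65. In other clusterings, the myonuclear cluster highest in Runx1 held 84.9% of cluster 22 at resolution 1.5 and 66.5% at resolution 0.4. It held 80.7% with doublets kept, 75.5% with every deposited barcode and 67.0% with at least 500 genes. Clustering without the list genes gave such a cluster with 52.4%, made of 1, 91 and 31 nuclei, or 0.0473%, 4.55% and 1.63%. With 15 principal components, the myonuclear cluster highest in Runx1 held 20.8% of cluster 22. It made up 3.08%, 4.85% and 3.42% of the libraries. Without the 100 leading genes of cluster 22, the one highest in Runx1 held 19.8% and made up 0.994%, 2.80% and 1.47%. These clusters took the names of tendon junction and neuromuscular junction myonuclei. Where the other nuclei of cluster 22 went was not measured. In the unnamed myonuclei of the aged vehicle library, Ankrd1, a stretch-induced gene, had 251 UMIs and Ablim1 278, against 0 in young vehicle for both.

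In type IIx/IIa myonuclei, Ablim1, an actin-binding gene, stood at 3.55 and Hectd2os at 2.45, while Cish was at -3.27, Fkbp5 at -2.71 and Socs2, another brake on growth hormone signalling, at -2.04. Pcdh9 was at 4.45 there but at -0.36 with 15 principal components. At the tendon junction, the sodium channel gene Scn2a stood at 3.72 and the fatty acid transporter Cd36 at 3.16, and Nkain2 at 1.82, while Dgkb was at -6.07 (1 UMI in aged vehicle), the potassium channel gene Kcnh7 at -3.95 and the synaptic gene Clstn2 at -2.42. In fibro-adipogenic progenitors the clock activators Arntl and Npas2 stood at 4.27 and 2.77 and the sodium leak channel Nalcn at 2.86, while Rtl4 was at -3.22, the clock repressor Per2 at -3.19 and Unc13c at -3.05. The clock list there had a median of -0.78 (percentile 0). In endothelial nuclei the guidance receptor Robo2 stood at 3.92 and Rasa4 at 2.31, and Gsn, which cuts actin filaments, at -2.68, the secreted protein Reln at -2.22 and Rbms3 at -2.10. The muscle gene Mybpc1 stood at 2.65 there, but at -0.34 at equal depth. Mural nuclei had the netrin Ntn4 at 1.59, the endothelin receptor Ednrb at 1.42 and the repressor Bcor at 1.37, and Gsn at -2.41 and Serpini1 at -2.05. Macrophages had the polarity gene Pard3b at 2.11, the TGF-beta receptor Tgfbr1 at 2.08 and Naaladl2 at 2.06. Adipocytes had Fabp4, their fatty acid carrier, at 2.10, the fatty acid elongase Elovl6 at 2.04 and Car5b at 1.74. The lowest ratios in macrophages and adipocytes were those of muscle genes: Dmd, Trdn and Ttn stood at -3.94, -3.69 and -2.08 in macrophages and at -2.88, -3.52 and -3.01 in adipocytes. In unnamed myonuclei Rian stood at -8.15, the noncoding RNA Meg3 at -7.81 and Fkbp5 at -2.76, and Cilp had 70 UMIs against 0 in young vehicle. Clusters 5 and 22 held 92 and 5 of these nuclei in young vehicle and 110 and 142 in aged vehicle. The ratios of this class therefore do not compare like nuclei.

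Clock genes chosen after their values were seen, and Fkbp5, were then set side by side in 9 classes. The activators Arntl, Clock and Npas2 summed were higher in aged vehicle, and the clock-output and repressor genes Dbp, Per3, Tef and Hlf summed were lower, in 9 of 9 classes. These sums stood on opposite sides in 8 of 9 classes for aged GB against young vehicle, and in 7 of 9, in both directions, for aged GB against aged vehicle, with 0.35 (0.10 to 0.60) and -0.26 in progenitors. In fibro-adipogenic progenitors the ratios of aged vehicle against young vehicle were 1.26 (0.94 to 1.59) and -1.30 (-1.52 to -1.09), and in type IIb myonuclei 0.48 (0.21 to 0.75) and -0.78 (-0.92 to -0.64). The fixed clock list had a median near 0 in macrophages (0.0244 over 4 members) and adipocytes (0.0774 over 9). In macrophages 2 of the members were at least 1.5-fold higher and 2 at least 1.5-fold lower, so this median hides differences on both sides. The first sum's interval holds 0 at the tendon junction and in adipocytes, and the second sum's in macrophages. Fkbp5 was lower in aged vehicle in all 9, from -0.39 in endothelial nuclei to -2.76 in unnamed myonuclei, with intervals that hold 0 in endothelial and mural nuclei.

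**Figure D5:**
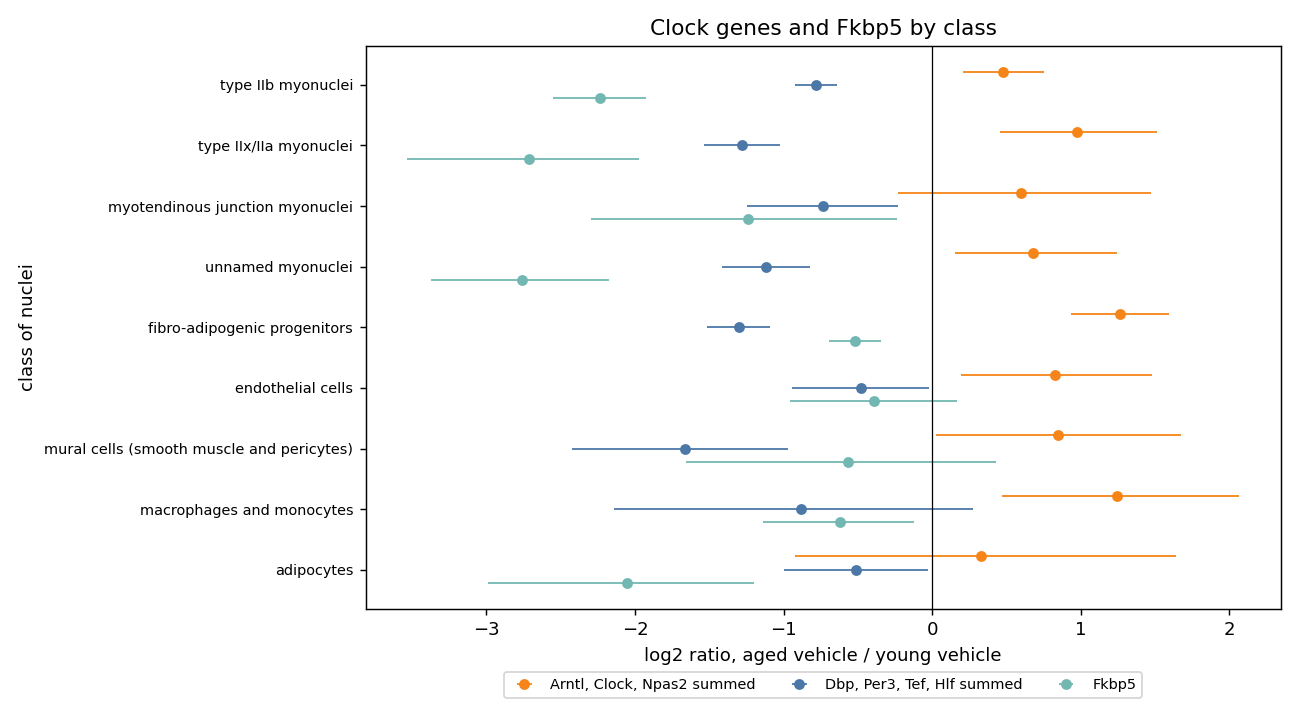
Log2 ratios of aged vehicle against young vehicle (x axis) in 9 classes of nuclei (y axis) for Arntl, Clock and Npas2 summed, for Dbp, Per3, Tef and Hlf summed, and for Fkbp5, with 95% intervals that cover counting error only. The first sum lies above 0 and the second below 0 in 9 of 9 classes.

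The second comparison, aged GB against aged vehicle, asks what the treatment did in aged muscle. In type IIb myonuclei of the GB library, the fatty acid list with Pdk4 and Ucp3 stood higher, as did Man1a, Nos1, Smad3 and Foxo1, and Fkbp5 was lower still. The receptor that GB blocks was detected in macrophages and not in myonuclei. Fewer genes stood 2-fold apart in type IIb myonuclei than between aged and young vehicle, at lower depth. In macrophages, where depth was higher, more did, with 19 higher and 10 lower against 4 and 5. Muscle marker UMIs in macrophages numbered 560 in aged GB and 123 in aged vehicle, so these counts can include muscle genes.

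Ptafr (ENSMUSG00000056529, chromosome 4, 132564067 to 132582683), which encodes the receptor of platelet-activating factor, had 0 UMIs in the myonuclei of all 3 libraries. At 1000 UMIs per nucleus the upper interval ends of the share are 0.368%, 0.359% and 0.466%. In macrophages 16.7%, 14.3% and 9.72% had a UMI at that depth, and Ptafr was at 170, 122 and 136 CPM, with intervals that overlap. Endothelial nuclei had none.

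In type IIb myonuclei, 26 of 2991 genes were at least 2-fold higher and 15 at least 2-fold lower in the GB library. The highest was Man1a (ENSMUSG00000003746, chromosome 10, 53904785 to 54076609), which trims mannose from glycoproteins, at 74.1 CPM in aged vehicle and 247 CPM in aged GB, a log2 ratio of 1.74 (1.40 to 2.09). The mitochondrial ATP carrier Slc25a25 stood at 1.66, Pde10a at 1.58 and the sarcomere gene Igfn1 at 1.53. Nos1 (ENSMUSG00000029361, chromosome 5, 117781032 to 117958840), the nitric oxide synthase of the muscle membrane, was at 166 and 477 CPM, a ratio of 1.52 (1.29 to 1.75). The TGF-beta transducer Smad3 stood at 1.44, and Foxo1, which drives atrophy genes and fat use, at 1.42 (1.25 to 1.60). The thin-filament gene Lmod2 stood at 1.42, Arhgap26 at 1.30 and Cnksr3 at 1.29. The lowest were Sorcs1, a sorting receptor, at -1.76 (-2.39 to -1.18), Naaladl2 at -1.61, the chromatin gene Arid5b at -1.32 and the hypoxia factor Epas1 at -1.32. Over all nuclei, Arid5b was at 0.05 and Epas1 at 0.37. Dusp10, a phosphatase of stress kinases, stood at -1.31, Fkbp5 at -1.26, Mreg at -1.25, Nin at -1.20, Adamtsl1 at -1.14 and Ostn, a secreted muscle factor, at -1.10.

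Pdk4 was at 396 and 888 CPM, a ratio of 1.16 (1.01 to 1.32), and the mitochondrial uncoupler Ucp3 at 203 and 488 CPM, a ratio of 1.27 (1.05 to 1.48). The fatty acid list had a median of 0.43 (percentile 99.98). Glycolysis was at -0.11 (percentile 1.60), insulin signalling at -0.16 (percentile 2.54) and calcium handling at -0.11 (percentile 3.54). The denervation list had a median of 0.71 over 5 members (percentile 99.8), but -0.26 with 15 principal components and -0.29 over all nuclei. Hdac4, which carries the signal of lost nerve activity, stood at 0.94 in it. Within the platelet-activating factor pathway Pla2g7, the enzyme that degrades the factor, was at 45.8 and 12.7 CPM, a ratio of -1.85 (-2.80 to -0.99), while the list's median was 0.06. The myosin Myh4 was at 4558 and 5311 CPM.

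Over all myonuclei Runx1 was lower in the GB library, at a log2 ratio of -0.65 (-0.83 to -0.47), while the denervation list without Runx1 stood at -0.03 (-0.32 to 0.27), with 6 of 12 members higher. The fatty acid list was at 0.50 (percentile 100) and the slow contractile list at 0.52 (percentile 100). The type IIb share of myonuclei differed here too, at 48.2% in aged vehicle and 43.9% in aged GB. Within type IIx/IIa myonuclei the slow contractile list was at 0.16 (percentile 75.6). Among single genes over all myonuclei, Acoxl, a peroxisomal oxidase, stood at 2.83, Fndc1 at 2.26 and Apba3 at 1.93. The potassium channel partner Kcnip4 stood at -4.46, the synaptic adhesion gene Nrxn3 at -2.16 and Galnt18 at -1.96. In unnamed myonuclei the stretch-responsive Ankrd2 stood at 1.83, Man1a at 1.74 and Txnip, which restrains glucose uptake, at 1.70. Peg3 stood at -2.46 there, Plxdc2 at -2.41 and Nabp1 at -2.19. Clusters 5 and 22 held 110 and 142 of these nuclei in aged vehicle and 129 and 65 in aged GB, so their makeup differed. In type IIx/IIa myonuclei Acoxl stood at 2.35, Man1a at 2.32 and Pde10a at 1.74, and Sel1l3 at -1.81 and Rcsd1 at -1.44. Pcdh9 had 56 UMIs there in aged vehicle and 0 in GB, but its ratio was 0.30 with 15 principal components. At the tendon junction Fam155a stood at 2.89, Ucp3 at 1.95 and the calcium channel subunit Cacnb4 at 1.89, and Nrxn3 at -4.92. Kcnip4 had 76 UMIs there in aged vehicle and 0 in GB. Agbl1 was at -2.88 there, but at 0.91 with classes from marker scores.

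Outside the fibres, fibro-adipogenic progenitors of the GB library had the matrix gene Postn at 2.87 (1.74 to 4.24), the metallothionein Mt2 at 1.86 and the actin regulator Wdr1 at 1.86, and Ctnna3 at -3.58, Fgf13 at -2.79 and the muscle gene Trdn at -2.22. The clock list there stood at 0.26 (percentile 98.6) and the extracellular matrix list at 0.04 (percentile 52.4). Endothelial nuclei had Emp1 at 2.97, Rbms3 at 2.07 and Plxdc2 at 2.35, although Plxdc2 was at -0.41 with classes from marker scores. Their lowest were the muscle genes Mybpc1 and Actn2 at -2.92 and -2.34 and the potassium channel gene Kcnma1 at -2.58. In aged vehicle, 8 of 152 endothelial nuclei held 62.2% of the muscle marker UMIs of that class. Mural nuclei had the matrix signal Ccn2 at 3.06, Pde10a at 2.34 and the protease Adamts9 at 1.91, and Dag1 at -1.90, Bcor at -1.69 and Ncald at -1.67. Adipocytes had the matrix signal Ccn1 at 5.36 (1 UMI in aged vehicle) and Thbs1 at 4.10, and the fat-synthesis genes Elovl6 and Acaca at -4.29 and -2.25 and Cyp2e1 at -1.80. Macrophages had the growth factor Igf1 at -2.04, Hdac8 at -1.68 and Naaladl2 at -4.08. Their highest were Sox5 at 5.07, although at -0.78 when clustered without 100 leading genes, the muscle gene Dmd at 4.01, and Prickle1, with 62 UMIs against 0 in aged vehicle.

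The third comparison, aged GB against young vehicle, asks how far the treated aged muscle stands from the young one. In type IIb myonuclei it stood farther away than the untreated aged library did. Of 3559 genes, 100 were at least 2-fold higher and 139 at least 2-fold lower. Pde10a stood at 3.71, Man1a at 3.13, Pdk4 at 3.12, the growth factor Fgf1 at 2.78 and Ucp3 at 2.51. Klf10, Dennd5b and Ppfibp2 stood at 2.54, 2.40 and 2.23, and Pcdh9 at 2.30 but -0.72 over all nuclei. Peg3 stood at -4.44, Fkbp5 at -3.50 (-4.04 to -3.00), Mettl21c at -3.16, Gpc5 at -3.02, Mlf1 at -2.53 and Acsl3, which activates fatty acids, at -2.47. Adamts20, the calcium-handling enzyme Dhrs7c, Pik3r1 and Sh3kbp1 stood at -2.24, -2.22, -2.09 and -2.04. The medians of the fatty acid, glycolysis and clock lists were 1.05, -0.49 and -0.48, each farther from 0 than in aged vehicle against young vehicle. Not all lists did so. Immediate early genes stood at 0.30 and calcium handling at -0.16, against 0.47 and -0.24 in aged vehicle against young vehicle. Over all myonuclei the denervation list was at 1.44 over 12 members and Runx1 at 3.90, with Sh3d19 at 4.63, Cilp at 4.34, Cish at -7.47 (1 UMI in GB) and Kcnip4 at -5.81. Rian had 123 UMIs in young vehicle and 0 in GB.

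The age and treatment ratios were then compared gene by gene, to ask whether genes that differ with age stood on the other side with treatment. They did not do so in general in type IIb myonuclei. Across 2970 genes the correlation of the ratios was -0.05 and the covariance -0.00677. Simulated unchanged libraries gave -0.52 and -0.0169, because both ratios share the aged vehicle library. With the aged vehicle nuclei split at random into separate sets for each ratio, the correlation was 0.10. Of 83 genes at least 2-fold apart with age, 37 (44.6%, 33.7 to 55.9) stood on the other side with treatment, and 38.5% did so after the split. With 15 principal components the share was 57.8%, and over all nuclei 64.2%. Over all myonuclei 128 of 243 genes (52.7%) stood on the other side, and 43.8% after the split. In fibro-adipogenic progenitors 29 of 54 (53.7%) did, and 38.2% after the split. Over all myonuclei and in progenitors the covariances were -0.0203 and -0.0317, against -0.0159 and -0.0230 in simulated unchanged libraries. After the split they were 0.00753 and 0.00339. Pdk4, Pde10a, Man1a and Fkbp5 in type IIb myonuclei stood on the same side in both comparisons. They were picked among the leading genes, and 37 of the 83 genes stood on opposite sides. Genes are not independent replicates, and the shared library remains in every one of these values.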

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

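All tests in this part were chosen after the results they address were seen. The mitochondrial list stood on opposite sides in 2 classes for aged GB against aged vehicle, at a median log2 ratio of 1.08 in macrophages and monocytes and -0.78 in mural cells, which drew attention as a difference between groups. Muscle marker transcripts were higher in the same macrophages, at 1.34 (560 against 123 UMIs), with 62.1% of these UMIs in 5 of the 102 aged GB macrophages, and fast contractile genes stood at 1.40. The difference in the mitochondrial list was not tested, each value rests on 5 members, and no explanation was tested for it.

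Runx1-high myonuclei came mostly from the aged libraries, with aged fibres that have lost nerve contact as the biological candidate. RNA of macrophages, which hold as much Runx1, is argued against: summed macrophage markers in the cluster were at 0.255% of their level in macrophages. A clustering effect as the cause of the higher denervation genes is argued against by the denervation list without Runx1, at a median log2 ratio of 1.20 over all myonuclei, and a depth effect by the 9.75% of aged vehicle myonuclei with a Runx1 UMI at equal depth against 0.699% in young vehicle. Whether these nuclei form a separate group stays open. When clustered without the cluster's 100 leading genes, which were chosen for it, 19.8% lay in the myonuclear cluster highest in Runx1. Where the others went was not measured, so this value does not decide the question. Age and other differences between the pools of mice cannot be told apart with 1 library per group, so ageing stays open and untested.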

How the results depend on the processing

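Alternatives were fixed before the data were examined, apart from clustering without the 100 leading genes of the Runx1-high cluster, chosen after the data were seen. Of 5177 gene ratios recomputed, 4761 stayed within their interval, 402 moved and 14 reversed. Of 1662 list medians, 1559 stayed, 97 moved and 6 reversed. A ratio could count as reversed only if it was at least 2-fold apart with an interval that excludes no difference. A list median could do so only if it was large. The values that moved can therefore include smaller ones that changed sign. Of 438 class shares 345 stayed, and of 165 shares of nuclei with a UMI 143 stayed. Of 24 shares of the myonuclear cluster highest in Runx1, taken anew in each clustering, 11 stayed. No paired analysis was possible because the libraries share no animal or batch label, and with 1 library per group none could be left out. For the values below that moved or reversed, the cause was not tested, apart from gene counts that follow the minimum or the depth by construction. Depth limits the genes measured: thinning and higher minimums leave fewer.

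The share of type IIb myonuclei moved with the clustering and with the nuclei kept. In young vehicle, aged vehicle and aged GB it was 37.5%, 39.4% and 28.4% with 15 principal components, 29.5%, 21.3% and 14.9% with at least 500 genes per nucleus, and 36.6%, 34.8% and 26.3% when clustered without list genes. It was 27.9%, 24.8% and 16.3% when clustered without the 100 leading genes, 36.7%, 34.5% and 26.5% with doublets kept, 28.7%, 23.4% and 15.8% with every deposited barcode, and 29.2%, 23.5% and 15.5% at resolution 1.5. With marker score classes it was 26.6% in aged vehicle. The share of neuromuscular junction myonuclei in aged vehicle was 7.10% with at least 500 genes and 6.83% with every deposited barcode, against 1.00%. The share of all myonuclei was 47.6%, 53.8% and 43.8% with marker score classes, and 52.0% in young vehicle with at least 500 genes. The share of myonuclei with a Runx1 UMI was 1.81%, 15.4% and 17.0% without thinning, and 6.86% in aged vehicle and 3.98% in aged GB at 500 UMIs.

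Genes at least 2-fold higher and lower in type IIb myonuclei, aged vehicle against young vehicle, numbered 110 and 80 with 15 principal components, 111 and 135 over all nuclei, 119 and 113 with a minimum of 10 and 50 UMIs, 32 and 31 with 50 and 200 UMIs, 2118 and 2921 with no minimum, and 25 and 30 when thinned to 1000 UMIs. For aged GB against aged vehicle, 169 were higher and 31 lower over all nuclei, 59 and 59 with a minimum of 10 and 50 UMIs, 2341 and 2552 with no minimum, and 17 and 7 when thinned, with 28 lower at 15 principal components and 5 lower at 50 and 200 UMIs. For aged GB against young vehicle, 182 were higher and 227 lower with 10 and 50 UMIs, 62 and 79 with 50 and 200 UMIs, 2206 and 3248 with no minimum, and 47 and 70 when thinned, with 289 higher over all nuclei.

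The correlation of the age and treatment ratios in type IIb myonuclei was -0.17 with 15 principal components, 0.10 with aged vehicle nuclei split at random, -0.26 over all nuclei, -0.13 without the 100 leading genes, -0.17 with a minimum of 10 and 50 UMIs, 0.0101 with 50 and 200 UMIs, and -0.39 with no minimum. The share of genes on opposite sides was 57.8% with 15 principal components, 64.2% over all nuclei, 59.1% without the 100 leading genes and 76.7% with no minimum.

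Over all nuclei instead of type IIb myonuclei, signs reversed for Chrm3 (-0.24) and Pcdh9 (-0.40) in aged vehicle against young vehicle, for Arid5b (0.0548), Epas1 (0.37) and Lama2 (-0.16) in aged GB against aged vehicle, and for Nfkbia (0.43) and Pcdh9 (-0.72) in aged GB against young vehicle. With 15 principal components Pcdh9 in type IIx/IIa myonuclei was at -0.36 in aged vehicle against young vehicle and 0.30 in aged GB against aged vehicle. With marker score classes, Agbl1 at the tendon junction was at 0.91 and Plxdc2 in endothelial nuclei at -0.41 in aged GB against aged vehicle, and Neb in mural nuclei at 2.07 in aged GB against young vehicle. Mybpc1 in endothelial nuclei was at -0.34 when thinned (aged vehicle against young vehicle), and Sox5 in macrophages at -0.78 without the 100 leading genes (aged GB against aged vehicle).

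The denervation list in type IIb myonuclei, aged GB against aged vehicle, was at -0.26 with 15 principal components, -0.29 over all nuclei and -0.0109 without the 100 leading genes. In aged vehicle against young vehicle, the circadian list in endothelial nuclei was at 0.37 when thinned, and the senescence list in fibro-adipogenic progenitors at 0.26 with a minimum of 10 and 50 UMIs and 0.0420 with no minimum.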

Other observations

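The fatty acid list, described above for type IIb and all myonuclei, also stood high in other fibre classes. In type IIx/IIa myonuclei its median log2 ratio was 0.41 in aged vehicle against young vehicle, 0.29 in aged GB against aged vehicle and 0.65 in aged GB against young vehicle. This class pools cluster 6, led by Myh1, with 122, 145 and 110 nuclei in young vehicle, aged vehicle and aged GB. It also holds cluster 7, with Myh2 among its leading genes, at 40, 82 and 78 nuclei. The makeup of the class therefore differed between libraries, and its effect on these medians was not tested. At the tendon junction the median of the fatty acid list was 1.25 in aged vehicle against young vehicle, with 9 of 10 members at least 1.5-fold higher. It was -0.11 there in aged GB against aged vehicle. Over all myonuclei the list of immediate early and handling stress genes stood at 0.43 in aged vehicle against young vehicle. It stood at 0.40 in aged GB against aged vehicle and 0.72 in aged GB against young vehicle. In fibro-adipogenic progenitors the senescence list stood at -0.59 over 5 members in aged vehicle against young vehicle, and at 0.49 in aged GB against aged vehicle. The first of these turned to 0.26 with a minimum of 10 and 50 UMIs.

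All tests in this part were chosen after the results they address were seen. Clock genes and Fkbp5 stood apart between the aged vehicle and young vehicle libraries in muscle and in some non-muscle nuclei. A state of the fibres alone is argued against by the fixed clock list in fibro-adipogenic progenitors, at a median log2 ratio of -0.78 (-1.06 to -0.46). The list was at -0.96 in mural nuclei, at -0.55 in endothelial nuclei but 0.37 when thinned, and near 0 in macrophages (0.0244) and adipocytes (0.0774). A median near 0 does not mean that the members were alike. In macrophages 2 of the 4 members were at least 1.5-fold higher and 2 at least 1.5-fold lower. In adipocytes 1 was higher by that measure, 4 were lower and 4 lay between. Activators and output genes stood on opposite sides in 9 of 9 classes, but these genes were picked for the pattern, so the count does not decide on collection at another phase of the daily cycle. With no collection time in the labels, collection time and age cannot be told apart, and both stay open.

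Muscle marker transcripts, summed without Dmd, stood apart between libraries in non-muscle nuclei, at a log2 ratio of 0.64 in fibro-adipogenic progenitors, 0.33 in endothelial nuclei, -0.77 in mural nuclei, -1.55 in macrophages and -2.66 in adipocytes for aged vehicle against young vehicle. More free muscle RNA in aged vehicle as the cause in progenitors is argued against by the ratio without the 5% of nuclei with the most, -0.17 (-0.34 to 0.0131 with nuclei resampled). Without these nuclei the ratio was also below 0 in endothelial nuclei (-0.32), adipocytes (-0.96) and macrophages (-0.51, -0.98 to -0.0731 with nuclei resampled). In macrophages this argues against more free RNA in young vehicle as the whole cause and leaves it open as a part. In aged vehicle progenitors, 20 of 394 nuclei held 66.2% of these UMIs, where an even spread at the same depths gave 15.1%, and 3 of 68 young vehicle macrophages held 60.2%, where it gave 11.8%. Among aged vehicle endothelial nuclei, 8 of 152 held 62.2%, where an even spread gave 17.5%. A few nuclei with attached fibre RNA, or doublets left after calling, may set these differences. Ratios of Trdn in progenitors, Mybpc1 and Actn2 in endothelial nuclei and Ttn in macrophages are therefore not read as expression.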
